A study of Mus musculus with 12 samples.

How the data were processed

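RNA from mouse testis was compared on 12 cDNA arrays, each hybridised with 2 RNA samples labelled with Cy3 and Cy5. Per the labels, each channel held a pool of RNA from 3 males on a Castaneus background. The pools came from wildtype mice, from Wobbler mice, or from Wobbler mice carrying a modifier. The 3 possible pairs were each hybridised on 4 arrays, and on 2 of these 4 the dyes were exchanged. The labelling protocol also mentions a reference pool of 6 control animals, which does not match the channel labels; the channel labels were followed. Nothing in the labels says whether the arrays of a comparison were made from separate pools. The p-values therefore measure the spread between arrays, which may be technical.

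The authors deposited 1 log2 ratio per spot and array. Scanner, background correction and normalization are not given in the sources used here. The log base was read from the values. After subtraction of 1 additive shift per array, 1.05% to 7.73% of spots lay at log2 of ratios of small whole numbers (up to 5, within 0.001), against 0.613% to 0.997% at offset positions. Of the 20 most repeated values of an array, 1 to 12 lay there, and on the arrays of Wobbler over wildtype only 2, 1, 2 and 3. The shift lay between -1.11 and -0.11. On each array 1 repeated value between 15.5 and 16.5 lay log2(100000) above the shift. It was read as a code for a spot without a usable denominator and treated as missing, on 22 to 165 spots per array. This departs from the plan to keep the deposited values unaltered, and was settled after the values were seen but before any test. No intensities were used here, so spots could not be filtered by signal and no intensity-dependent correction was possible. An alternative left out the spots at the whole-number ratios above, taken as dim.

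The direction of the deposited ratios is not stated. The rule fixed beforehand compared how well the 3 comparisons closed their loop when values were read as Cy5 over Cy3 or as channel 1 over channel 2. Across 14975 probes the loop correlation was 0.178 for the first reading and 0.0104 for the second, so the values of dye-exchanged arrays were multiplied by -1. All ratios are given as the first-named genotype over the second. Which sign means higher rests on the array titles and on the usual order of the dyes, and is only likely.

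Of 20355 probes, 14030 had 1 gene symbol in the platform annotation, 5 had several and 6320 had none. Gene identifiers were compared with a gene table of assembly GRCm38.p6, which held all but 36 and changed 0 symbols. Probes with the same symbol were averaged per array, and a probe without a single symbol stayed a feature of its own. Of 16255 features, 14729 had a value on at least 3 of 4 arrays of every comparison and were tested; 9139 of these had a gene name. Each array held 18325 to 19584 usable spots. The number of arrays limits the precision.

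The log2 ratios were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 1 mean per comparison and 1 dye term per feature over all 12 arrays. An SE given for a gene is that of this fit, with 1 spread per feature over all 12 arrays. The n beside it counts the arrays of the comparison, and the SE does not measure the spread of those arrays alone. The Benjamini-Hochberg adjusted p had to lie under 0.05 within a comparison. Gene lists were tested with camera (inter-gene correlation 0.01), adjusted over all lists and comparisons, and also with an estimated correlation and with fry, whose directional test is meant unless the mixed test is named. Lists with under 5 measured members got no test. The lists covered cell types of the testis (acrosome, late spermatid, meiotic spermatocyte, spermatogonia, Sertoli, Leydig, peritubular and vessel, macrophage), epididymis, blood, Golgi traffic, lysosome, stress proteins, chaperonin, sterol synthesis, apoptosis, ribosomal proteins, oxidative phosphorylation and neighbours of Vps54.

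Genes were named by a rule. Per comparison it took up to 12 in each direction with the largest log2 ratio among named features past the threshold, with the same sign on all 4 arrays. It added up to 4 members of each list with the smallest p. The lists, the rule, the fit and most alternatives were fixed before the data were examined. The alternatives changed centring, scaling, the dye term, the filter, the model, the weights and the set of arrays.

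The fit was tested on simulated data made from the arrays' residuals with 200 changed features per comparison in 10 runs. At 4-fold, 80.0% of changed features were recovered in Wobbler over wildtype, 77.3% in modifier over wildtype and 78.0% in modifier over Wobbler. At 2-fold the shares were 50.3%, 42.9% and 47.7%, and at 1.5-fold 16.5%, 8.53% and 13.1%. Unchanged features made up 38.8%, 3.70% and 18.8% of the calls. In these simulations the error rate was therefore held in modifier over wildtype and exceeded in the other comparisons. The shares depend on the number of changed features put in. The fit shares 1 spread per feature, while the median residual SD was 0.46, 0.28 and 0.38 in the 3 comparisons.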

Results

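Testis RNA of wildtype mice, Wobbler mice and Wobbler mice with a modifier was compared directly in all 3 pairs, with 4 two-colour arrays per pair. Wobbler is a recessive missense mutation of Vps54, a subunit of a tethering complex for vesicles returning to the Golgi, and homozygous males are infertile with misshapen sperm heads. No probe was named for Vps54, so it has no value here. Array medians lay between 0.03 and 0.22 on the log2 scale and array SDs between 0.62 and 1.61. The widest array was replicate 2 of Wobbler over wildtype, with 13.9% of its deposited log2 ratios above 2.

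The first question was how testis with the modifier differed from wildtype testis. Transcripts of late spermatids were lower with the modifier, the direction being likely from array titles and dye order. Prm2 and Prm1, the protamines that package sperm DNA, had log2 ratios of -1.60 ± 0.21 (SE, n = 4) and -1.15 ± 0.16 (SE, n = 4). Tnp1, a transition protein that precedes the protamines, was at -1.10 ± 0.13 (SE, n = 4). Cyp17a1, an enzyme of androgen synthesis in Leydig cells, had the largest fall among named genes, -2.03 ± 0.17 (SE, n = 4), or 4.08-fold.

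Of 38 measured genes of the late spermatid list, 11 were lower, 0 were higher and 27 did not pass; adjusted over the list alone, 21 were lower. The list's median was -0.72, with a camera adjusted p of 3.09e-35 and an adjusted p of 0.0081 with an estimated correlation. Smcp, of the sperm mitochondrial capsule, was at -1.12, Oaz3, a spermatid antizyme, at -1.28, and Pgk2, the glycolytic kinase of male germ cells, at -1.02. The 2 probes of Prm2 gave -1.58 and -1.63. Further named genes with lower ratios were Dbil5 (-1.35), Spz1 (-1.33), Amigo2 (-1.28), Uck1 (-1.26), Mtdh (-1.25), Cypt1 (-1.21) and Cuzd1 (-1.19). Dbnl, an actin-binding protein, was the named gene with a higher ratio, 0.54 ± 0.10 (SE, n = 4).

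The Leydig list also fell. Its median over 13 genes was -0.33, with 2 genes lower, 0 higher and 11 not passing, and 3 lower adjusted over the list alone. The camera adjusted p was 8.47e-07, and the adjusted p was 0.014 with an estimated correlation. Ephx1, a hydrolase of epoxides, was at -0.77 beside Cyp17a1.

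Smaller shifts were found in 3 other lists. The acrosome list had a median of -0.20 with 0 of 22 genes passing, or 4 lower adjusted over the list alone (camera adjusted p 0.000129, adjusted p 0.0495 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.21, and 1 of 78, Atp5c1 at -0.65, passed; adjusted over the list alone 4 were lower (camera adjusted p 1.62e-08, adjusted p 0.0495 with an estimated correlation). Ribosomal proteins had a median of -0.22, and 1 of 57 passed, Rpl39l at -0.79, a paralog used in male germ cells; adjusted over the list alone 5 were lower. Their camera adjusted p of 1.03e-08 was lost with an estimated correlation (adjusted p = 0.107 with an estimated correlation). Outside these lists Syce2, of the synaptonemal complex (-0.94), Tyrobp, an adaptor of macrophages (-0.68), and Ctsh, a lysosomal protease (-0.64), passed, while the meiotic, macrophage and lysosome lists did not pass with camera. With the directional test of fry 7 lists passed in this comparison, all lower, among them the meiotic (adjusted p 0.0339) and Sertoli (adjusted p 0.00402) lists.

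In all, 108 of 14729 features passed in modifier over wildtype, 5 higher and 103 lower, with limma; 64 had a gene name. All 108 had the same sign on every array that measured them. The count fell to 20, 21, 20 and 49 without replicates 1 to 4 of this comparison, was 4 when its 4 arrays were fitted alone, and was 492 (77 higher, 415 lower) with arrays scaled to equal spread. Read as channel 1 over channel 2, no swapped array being turned, 0 features passed.

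**Figure D1:**
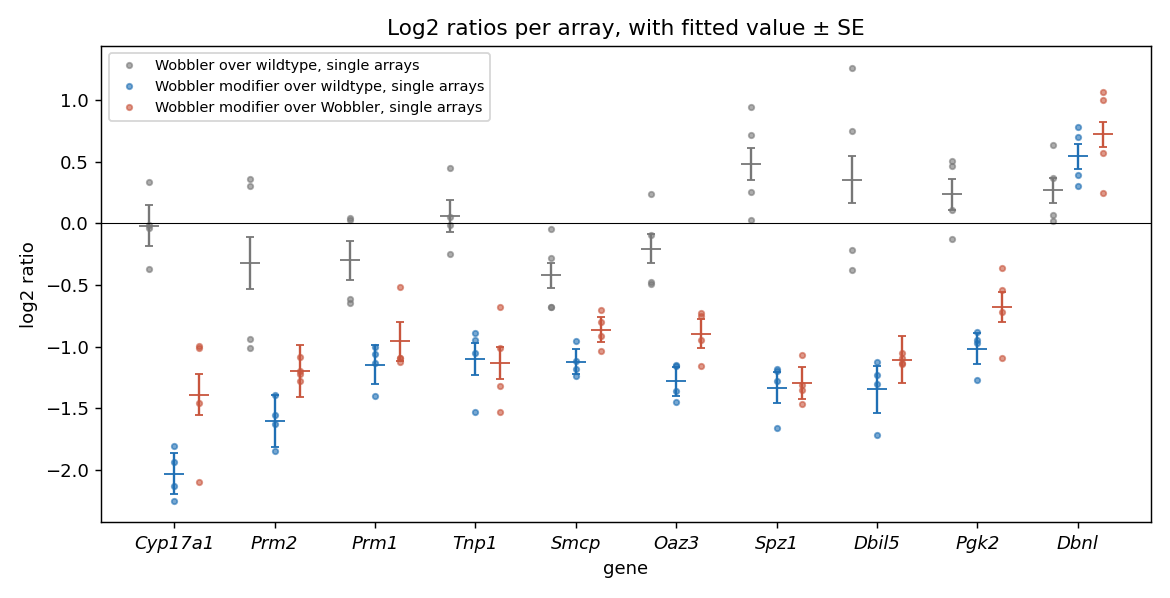
Log2 ratios of named genes (vertical axis, log2 units) in the 3 comparisons; points are single arrays, and dashes with bars are fitted values ± SE over 4 arrays. Prm1 is at -1.15 in modifier over wildtype and -0.96 in modifier over Wobbler.

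The next comparison asked how testis with the modifier differed from Wobbler testis without it. The same late spermatid and Leydig lists were lower. Tnp1 was at -1.13 ± 0.13 (SE, n = 4), Prm1 at -0.96 ± 0.16 (SE, n = 4), Smcp at -0.86 and Oaz3 at -0.90. Cyp17a1 was at -1.39 ± 0.17 (SE, n = 4).

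Of the 38 late spermatid genes, 6 were lower, 0 higher and 32 did not pass; adjusted over the list alone, 17 were lower. The median was -0.42, the camera adjusted p 8.69e-20, and the adjusted p 0.014 with an estimated correlation. The Leydig list had a median of -0.45, with 1 of 13 genes lower and 3 adjusted over the list alone (camera adjusted p 6.04e-06, adjusted p 0.014 with an estimated correlation). The acrosome list (median -0.21, 0 of 22 passing), the ribosomal proteins (-0.05, 0 of 57) and oxidative phosphorylation (-0.04, 0 of 78) passed with camera adjusted p of 0.00457, 0.004 and 0.0199. All 3 were lost with an estimated correlation, with adjusted p of 0.163, 0.484 and 0.345. Without replicate 1 of this comparison camera called only the late spermatid and Leydig lists, 2 in all, and without replicate 3 it called 4, oxidative phosphorylation being lost.

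The lowest ratio of a named gene was that of Mrpl30, a mitochondrial ribosomal protein, at -1.94 ± 0.31 (SE, n = 4). Others were Cuzd1 (-1.36), Spz1 (-1.30), Dbil5 (-1.11), Amigo2 (-1.01), Mtdh (-1.0), Uck1 (-0.95), Rfc4, a clamp loader of replication (-0.92), and Kash5, which links meiotic chromosome ends to dynein (-0.90). Gsta4 was at -0.85, but its probes gave -0.28 and -1.43. Higher ratios were those of Ctxn1 (1.48), Lat (1.41), Mfap5 (0.86), Crcp (0.79) and Dbnl (0.72). The probes of Lat gave 2.22 and 0.59.

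In all, 61 of 14729 features passed in modifier over Wobbler, 17 higher and 44 lower, and 33 had a gene name. Of these 61, 60 had the same sign on every array that measured them. In simulated data for this comparison with 200 changed features, 21.7 of 115.3 calls, or 18.8%, were unchanged features on average. That share depends on the number of changes put in and gives no error rate for the 61 calls. The count was 7, 0, 23 and 25 without replicates 1 to 4 of this comparison, 24, 25 and 35 without replicates 1, 2 and 4 of modifier over wildtype, and 128 and 40 without replicates 2 and 4 of Wobbler over wildtype. It was 101 with arrays centred on their medians, and 0 with its 4 arrays fitted alone.

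The modifier comparisons shared 44 features with the same direction, 40 lower and 4 higher, where independent lists would share 0.308 and 0.00577. Both lists come from 1 fit with 1 spread per feature, which by itself favours calling the same features, so they are not independent. The shared count was 6, 0, 17 and 22 without replicates 1 to 4 of modifier over Wobbler, and 19, 18, 19 and 24 without those of modifier over wildtype. It was 71 and 29 without replicates 2 and 4 of Wobbler over wildtype, and 0 with each comparison fitted alone. Of the 44, 25 had gene names, among them Cyp17a1, Prm1, Tnp1, Smcp, Oaz3 and Spz1. All 103 features lower against wildtype had negative ratios against Wobbler, with a median of -0.70. Both comparisons contain modifier RNA, and chance values of a shared pool would add to the overlap. The correlation of their ratios across features was 0.226 (covariance 0.0273). Simulated unchanged groups gave -0.000890 (covariance -0.000102) with no pool variance and 0.335 (covariance 0.111) with a pool variance of 0.25 times the array variance. Such pools of all 3 genotypes would also have given 0.333 between Wobbler over wildtype and modifier over wildtype, -0.332 between Wobbler over wildtype and modifier over Wobbler, and 0.578 between direct and indirect ratios. The observed values were -0.0302, -0.00996 and 0.124, which go against equal sharing of that size. The covariance simulated for that size, 0.111, was already above the observed 0.0273. Sharing small enough to give the observed covariance was not simulated, so it is not excluded. The simulation also gave all 3 comparisons the same array noise, unlike the data. Sharing of modifier pools alone was not simulated.

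The remaining comparison asked what the Wobbler mutation alone changed. With camera 0 of 18 tested gene lists passed, 1 at an unadjusted p under 0.05, and 0 passed with an estimated correlation or with the directional test of fry. The mixed test of fry, which asks for changes in either direction, called 10 of 17 lists here, 9 in modifier over wildtype and 8 in modifier over Wobbler. In Wobbler over wildtype its adjusted p was 1.19e-07 for ribosomal proteins, 4.11e-06 for the meiotic list, 0.00189 for Sertoli and 0.00432 for oxidative phosphorylation. The test uses 1 spread per feature from all 12 arrays. The median residual SD was larger here (0.46) than in modifier over wildtype (0.28) and modifier over Wobbler (0.38). Noise alone could therefore lower these mixed p-values, which was not tested. Without replicate 4 of this comparison the peritubular and vessel list, median 0.19 over 19 genes on all arrays, passed with a mean of 0.24 (adjusted p 0.046). The late spermatid list had a median of 0.02 with 0 of 38 genes passing, and the Leydig list 0.08 with 0 of 13. Single features did pass: 45 of 14729 (2310 at an unadjusted p under 0.05), 18 higher and 27 lower, of which 22 had a gene name. The split by direction was not stable: without replicates 1 to 4 of this comparison 29, 9, 5 and 10 were higher and 25, 20, 13 and 28 lower. Of the 45, 28, 23, 18 and 23 were called again. Fam81a had the highest ratio, 2.85 ± 0.30 (SE, n = 4), and Znf41-ps the lowest, -2.45 ± 0.12 (SE, n = 4).

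Other higher ratios were those of Tmem255a (2.12), Frat2 (1.63), Btk, a kinase of B cells (1.43), Haus4, of the spindle augmin complex (1.25), Tnfsf11 (1.16), Smim24 (0.76), P2rx1 (0.70) and Hnrnpa2b1 (0.64). Lower ratios were those of Klf16 (-1.72), Adgrl4, an adhesion receptor of endothelium (-1.70), Trip6 (-1.65), Cep83 (-1.39), Kcnn4 (-1.30), Serpina1f (-1.15), H1f6, the testis linker histone (-1.14), Phip (-1.02), Rps18 (-1.0), Usp53 (-0.99) and Upb1 (-0.79). Where a gene had 2 probes they differed: Cep83 gave -2.66 and -0.11, Kcnn4 -2.36 and -0.23, Phip -1.5 and -0.32, and Usp53 -1.46 and -0.52.

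These 45 ratios were not found by the indirect route. The 27 lower features had a median of -1.14 directly and -0.03 as modifier over wildtype minus modifier over Wobbler; the 18 higher features had 1.21 and -0.21. The slope of indirect on direct ratios was 0.0208 ± 0.0301 (SE). For the 108 features of modifier over wildtype it was 0.895 ± 0.0497 (SE), and for the 61 of modifier over Wobbler 0.650 ± 0.0781 (SE). The 103 lower features of modifier over wildtype had medians of -0.92 directly and -0.64 indirectly, and the 5 higher ones 0.88 and 0.89. In modifier over Wobbler the 44 lower ones had -0.91 and -0.99, and the 17 higher ones 0.77 and 0.26. A model with 2 genotype coefficients for the whole loop called 0 features in Wobbler over wildtype, 224 in modifier over wildtype and 207 in modifier over Wobbler. In simulated data with 200 changed features, 61.6 of 158.8 calls in Wobbler over wildtype, or 38.8%, were unchanged features on average. That share depends on the number of changes put in and gives no error rate for the 45 calls. The count was 0 with the 4 arrays fitted alone, 21 with array weights, and 29 and 18 without replicates 2 and 3; without replicates 1, 2 and 3 of modifier over wildtype it was 29, 28 and 28.

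**Figure D2:**
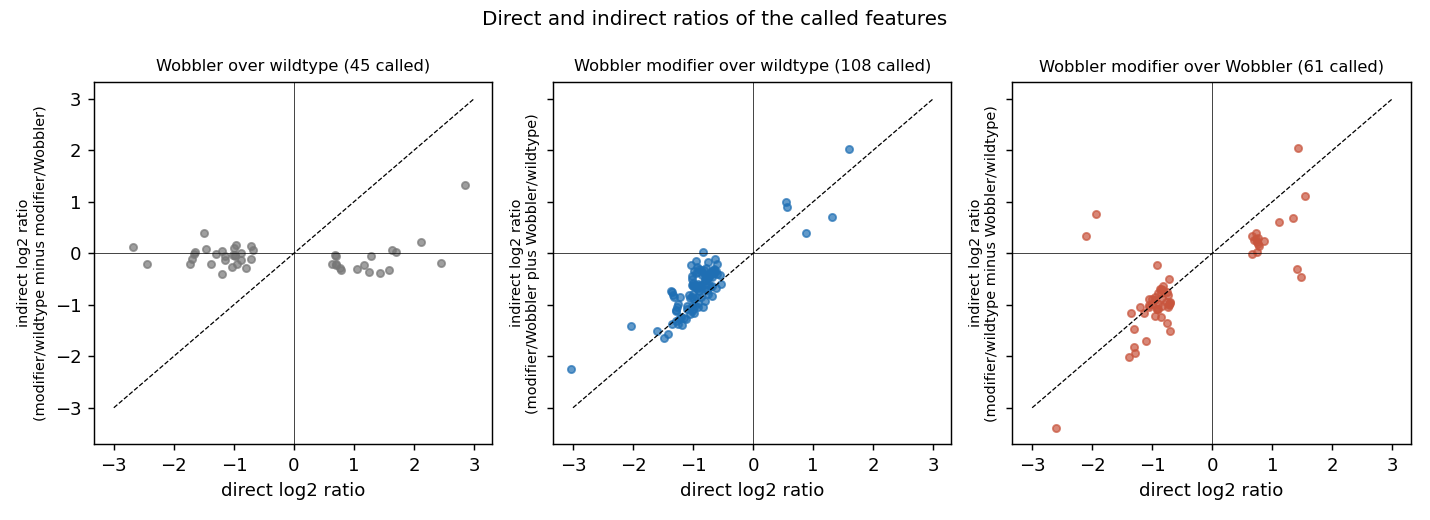
Direct log2 ratio (horizontal) against the indirect ratio from the other comparisons (vertical) for the called features of each comparison; the dashed line marks equal values. The 45 features of Wobbler over wildtype lie near the horizontal apart from Fam81a, with a slope of 0.0208, and those of modifier over wildtype have a slope of 0.895.

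With these values, little can be said of whether the modifier turned back changes of Wobbler testis. Of the 45 features, 27 had the opposite sign in modifier over Wobbler, 7 of the 18 higher and 20 of the 27 lower ones. The median ratio of all features in modifier over Wobbler was 0.078, which by itself favours opposite signs for lower features. Wobbler RNA is on opposite sides of these 2 ratios, so chance values of a shared pool would also favour opposite signs. The 18 higher features had medians of -0.20 in modifier over wildtype and 0.02 in modifier over Wobbler, and the 27 lower ones 0.02 and 0.13. Of the features called in Wobbler over wildtype, 0 were shared in the same direction with either modifier comparison. In the opposite direction 1 lower feature was called higher in modifier over wildtype (0.00917 by independence) and in modifier over Wobbler (0.0312). It was the same unnamed probe in both, and calls from 1 fit with 1 spread per feature are not independent. Across all 14729 features the direct modifier-over-Wobbler ratio correlated with the indirect one at r = 0.124 (rho = 0.150), features not being independent replicates. Their median difference was 0.09, and 4 features differed at an adjusted p under 0.05.

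**Figure D3:**
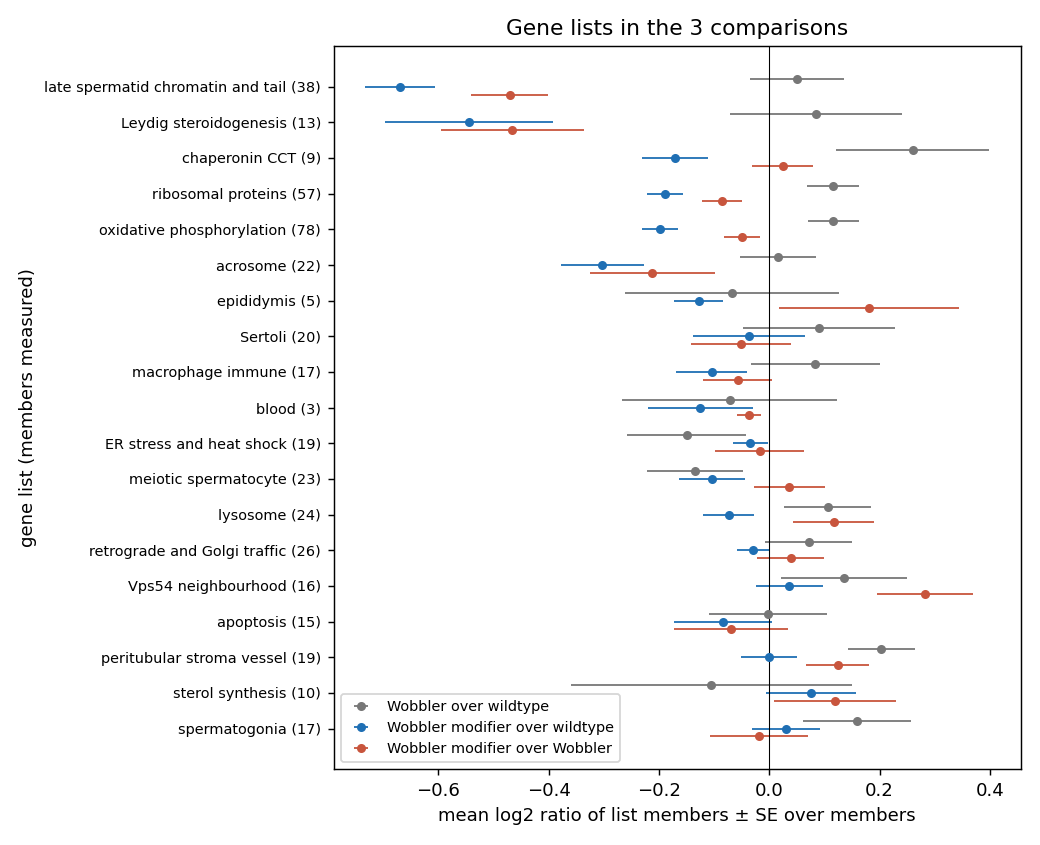
Mean log2 ratio of the members of each gene list (horizontal axis, log2 units, bars ± SE over members) in the 3 comparisons, with the number of measured members in parentheses. The late spermatid list lies at -0.67 in modifier over wildtype, -0.47 in modifier over Wobbler and 0.05 in Wobbler over wildtype.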

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

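The tests of common dye bias, of the reading of the ratios, of the late spermatid mean in Wobbler over wildtype and of the indirect Wobbler ratio were chosen after the results were seen. Among 4-array groups, 1 array stood far from the others in 8 of 96 groups examined, where chance flags about 1 in 20. In Wobbler over wildtype, Fam81a was at 3.81 on replicate 2 and at most 2.65 on the others. In modifier over Wobbler, Cuzd1 was at -1.79 on replicate 1, Prm1 at -0.51 on replicate 3 and Rfc4 at -1.17 on replicate 3. In modifier over wildtype, Syce2 was at -1.27 on replicate 3 and Atp5c1 at -1.01 on replicate 4. The share of spots with a deposited log2 ratio above 2 was 13.9% on replicate 2 of Wobbler over wildtype, and 1.16% on replicate 3 of modifier over wildtype.

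For 4 features the direct and indirect modifier-over-Wobbler ratios differed. The difference was -2.23 for Znf41-ps, 1.82 for Btk, and 1.90 and -2.80 for the unnamed probes 1228 and 16995. All 4 were called in Wobbler over wildtype, and their direct modifier-over-Wobbler ratios were 0.24, 0.14, 0.19 and 0.0015.

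The 45 calls in Wobbler over wildtype had the same sign on every array that measured them. They were selected on their mean over these same arrays, which favours this and shows no repetition. Along the loop they were not found. A Wobbler and wildtype difference present in every pool would need a slope of at least 0.5, and the slope was 0.0208, which argues against it as the whole cause. Without replicate 2 there were 29 calls, 23 of them among the 45, and the count lay between the bounds set beforehand for and against noise of that array. Unequal spread between comparisons gave 8 calls on average in simulations without any change, fewer than the 45, but a simulated bound excludes nothing by itself. The comparison fitted alone called 0, but that fit also lacked the dye term and had fewer residual degrees of freedom. Unequal spread is therefore neither shown nor excluded. Pools of different animals in these 4 arrays stay open and were not tested.

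Late spermatid transcripts were lower in both modifier comparisons. A dye bias common to all arrays is argued against by a slope of -0.0230 ± 0.0151 (SE) between half-differences of the dye orientations. Such a common bias would give a positive slope, near 1 without noise. Noise of the half-differences would lower it by an amount that was not estimated. A reading as channel 1 over channel 2 stays open. The shifts were negative on all 12 arrays, but their mean was -0.77 with Cy5 in channel 1 and -0.49 with Cy3 (exact permutation p = 0.037). The loop correlation and the rho between probes of 1 gene were higher for the reading used. A dye bias limited to the modifier arrays could raise both. That rho was 0.157 against 0.0441 in modifier over wildtype and 0.0839 against -0.0218 in modifier over Wobbler. In Wobbler over wildtype it was 0.0140 against -0.0112, so probes of 1 gene hardly correlated there under either reading. Under the reading used a dye bias of abundant transcripts would cancel. The late spermatid means were -0.86 to -0.55 and -0.64 to -0.33 on the 4 arrays of each modifier comparison, with both dye orientations. Such a bias therefore stays open only with the other reading. Ribosomal proteins had medians of -0.22 in modifier over wildtype and -0.053 in modifier over Wobbler. Set against the median of all features (0.012 and 0.078), they had -0.23 and -0.13, and late spermatid genes -0.73 and -0.49. In Wobbler over wildtype such a bias would also act. The late spermatid list had array means there of 0.42 and 0.13 with Cy5 in channel 1, and -0.26 and -0.18 with Cy3. Its mean was 0.051 (SE 0.0853 over members, 0.155 over arrays). With the values known, 6 pairings of a bound (-0.12, -0.24 or -0.47, fractions of the modifier-over-Wobbler mean or all of it) and an SE were tried; the mean lay over 2 SE above the bound in 3, but with neither SE for -0.12. Fewer late spermatids among the cells was neither shown nor excluded. It called for all 4 lists of other cell types to lie above the median of all features in modifier over wildtype. Spermatogonia (0.076) and peritubular and vessel genes (0.031) lay above it, while Sertoli (-0.10) and Leydig (-0.35) lay below. Only Leydig lay below by over 2 SE, where 2 such lists had been set as needed to argue against this explanation.

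For each comparison the 4 arrays allow 8 sign patterns, too few for a share under 0.05. The pattern used gave 45, 108 and 61 calls in Wobbler over wildtype, modifier over wildtype and modifier over Wobbler, and the highest of the others 1 in each. For the features called in both modifier comparisons, 1 of 100 sign patterns of the 8 arrays, the pattern used, gave 44, and the highest of the others 0, which excludes chance only in the sense of random array signs. That pattern was itself picked from 2 readings of the ratios by a loop correlation on the same arrays, and chance values of shared pools are not covered.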

How the results depend on the processing

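Counts below are in the order Wobbler over wildtype, modifier over wildtype, modifier over Wobbler. The reading as channel 1 over channel 2, the kept codes, the removal of spots at small whole-number ratios, taken as dim, and the fit of the 8 modifier arrays were chosen after seeing the data; the cause of the changes was not tested. Arrays centred on their medians gave 101 calls in modifier over Wobbler and 69 shared by the modifier comparisons. Scaled arrays gave 23 and 492 calls in the first 2 comparisons and 69 shared. Without the dye term the counts were 24, 46 and 7, with 6 shared. The loop model gave 0, 224 and 207, with 147 shared. Each comparison fitted alone gave 0, 4 and 0, with 0 shared. That fit has no dye term and fewer residual degrees of freedom. Every probe on its own gave 87, 165 and 110. Array weights gave 21 and 752 in the first 2 comparisons; in simulated data with weights 13.2%, 16.1% and 16.5% of calls were unchanged features. A replicate block in place of the dye term gave 22, 58 and 24, with 19 shared. Deviations of arrays of the same number correlated at r from -0.0286 to 0.0653 (mean 0.0256, against -0.0087 for other pairs). Arrays of the same number always share the dye orientation and most other pairs do not, so these means also differ by dye effects. Other pairs with the same orientation ran from -0.00952 to 0.120. No clear pairing by number was seen, but weak sharing of pools could go unseen. A shared Wobbler pool would lower r between Wobbler over wildtype and modifier over Wobbler, so the mean could hide it. Leaving out 1 array gave ranges of 18 to 54, 20 to 154 and 0 to 128, and 0 to 71 shared. Over these, the loop correlation ran from 0.0624 to 0.153, the share of Wobbler calls with opposite sign in modifier over Wobbler from 51.9% to 71.1%, and the lists called from 0 to 1, 5 to 5 and 2 to 5. With codes kept the loop correlation was 0.0718 and the oxidative phosphorylation mean in modifier over Wobbler 0.000236. An estimated correlation and the directional fry test each called 2 lists in modifier over Wobbler. Among the 1498 most variable probes the loop correlation behind the direction was 0.0801. Without the spots taken as dim the counts were 42, 112 and 65. Limits of signal over background could not be examined, since no intensities were used.

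Read as channel 1 over channel 2, all 3 counts, the shared calls and the lists called were 0 and the loop correlation 0.00670. List means then turned in modifier over wildtype (late spermatid 0.10, Leydig 0.083, acrosome 0.12, ribosomal 0.10, oxidative phosphorylation 0.14) and in modifier over Wobbler (late spermatid 0.080, Leydig 0.12, acrosome 0.075, ribosomal 0.12, oxidative phosphorylation 0.15). Genes whose sign turned were, in Wobbler over wildtype, H1f6 0.067, Kcnn4 0.087, Phip 0.15, Rps18 0.23, Trip6 0.065, Usp53 0.23, Znf41-ps 0.011. In modifier over wildtype they were Amigo2 0.25, Atp5c1 0.13, Ctsh 0.21, Cyp17a1 0.16, Cypt1 0.33, Dbil5 0.17, Ephx1 0.064, Mtdh 0.13, Oaz3 0.13, Pgk2 0.10, Prm1 0.053, Prm2 0.13, Rpl39l 0.22, Smcp 0.087, Spz1 0.10, Syce2 0.12, Tnp1 0.19, Tyrobp 0.23, Uck1 0.22. In modifier over Wobbler they were Amigo2 0.19, Cyp17a1 0.16, Gsta4 0.28, Kash5 0.22, Lat -0.20, Mfap5 -0.017, Mtdh 0.19, Oaz3 0.059, Rfc4 0.081, Smcp 0.11, Spz1 0.088, Tnp1 0.29, Uck1 0.067. Under the other settings 0 named genes turned their sign. Leaving out 1 array at a time ended 81, 61 and 104 calls of named genes in the 3 comparisons, summed over the 12 arrays.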

Other observations

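The test of neighbours of Vps54 was planned before its result was seen. Lists of other cell types and functions that did not pass with camera had these medians in modifier over wildtype: 0.09 for spermatogonia, 0.04 for peritubular and vessel genes, -0.09 for Sertoli cells, -0.07 for macrophages, -0.03 for meiotic spermatocytes and -0.03 for lysosome. With the directional test of fry the Sertoli and meiotic lists passed as lower. Golgi traffic, the pathway of Vps54, had medians of -0.04 in Wobbler over wildtype, 0.0030 in modifier over wildtype and 0.01 in modifier over Wobbler, with 0 of 26 genes passing. The mixed test of fry had an adjusted p of 0.00579 for it in Wobbler over wildtype, where larger noise of the arrays could by itself lower this value. Stress proteins had -0.06, chaperonin -0.22, sterol synthesis 0.08 and apoptosis 0.03 in modifier over wildtype. Chaperonin passed with camera when every probe stood on its own (mean -0.23, adjusted p 0.00279), making 6 lists. With genes averaged its camera adjusted p was 0.202, and 0.559 with an estimated correlation. Epididymis, with 5 measured genes, had -0.15, and blood, with 3 and no test, -0.06.

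A hypothesis was that strain variants linked to Vps54 would put called genes among its neighbours in gene order. Of 52 tested genes among the 100 nearest neighbours, 0 were called in Wobbler over wildtype, against 22 of 9087 others (one-sided Fisher's exact p = 1). With 22 calls in all, few would fall among 52 genes, so such linked variants stay open as a possible explanation for single genes. At an unadjusted p under 0.05 (limma) were 8, 2 and 12 of the 52 in Wobbler over wildtype, modifier over wildtype and modifier over Wobbler. Of all 14729 features, 2310, 1080 and 1694 were. These counts were not tested against each other. The list of 16 genes near Vps54 fixed beforehand had a median of 0.26 in modifier over Wobbler and a camera adjusted p of 0.202.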
